A study of Mus musculus with 8 samples.

How the data were processed

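Mouse splenic CD8 T cells were measured after culture in medium conditioned by B16F10 cells, a mouse melanoma line. Per the labels' protocols, the tumour cells either carried a knockout of SSBP4 or were wild type for it, and their medium was collected after 48 hours. T cells from C57BL/6 spleens were enriched by negative selection with a kit, cultured for 48 hours in 200 µl of that medium with antibodies against CD3 and CD28 at 2 µg/ml, and harvested for total RNA. The RNA was hybridised to the nCounter Myeloid Innate Immunity panel, an assay that counts barcoded probes bound to each transcript without amplification. There were 4 samples in wild-type medium and 4 in knockout medium. The series design calls them biological samples, but nothing says that they came from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical. The titles do not tell apart tumour clones or batches of medium within a group. A difference of clone or batch between the groups could thus not be parted from the knockout.

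The deposited signal table holds 754 genes and 14 control probes, 6 of them positive and 8 negative, for all 8 samples, and the software and normalization that the authors used are not given in the sources used here. The values themselves show part of it. In each sample the deposited gene values were whole multiples of 1 factor, within a tolerance of 0.1 of a step, for 100% of the values above 1 in 7 samples and for 99.87% in knockout medium sample 1. Values that would lie below 1 were listed as 1, and the control probes were left as whole, unscaled counts. The factors ran from 0.792 to 1.33 and stood at a ratio of 1.0 to 1.0001 to the product of a positive-control factor and a factor from the geometric mean of 20 reference genes, so that those 20 genes had a geometric mean of 530.06 to 530.07 in every sample. Of the gene names, 744 matched a current symbol in the RefSeq annotation of GRCm38.p6, 9 matched an older symbol and 1 was not matched.

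Dividing by the factor gave whole counts, whose totals ran from 188174 to 346676 per sample. These counts limit the precision of low genes, and a value near the negative controls is not told apart from background. The background threshold was the mean plus 2 SD of the negative control counts over all samples, 22.08. Genes with a mean over the 8 samples of at least this threshold were tested, which left 454 genes and set aside 300. The threshold comes from unscaled controls and was applied to scaled values.

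The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(value + 1), with knockout medium against wild-type medium as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. All fold changes are on the log2(value + 1) scale, which understates the change of low genes. Where the mean of a group lay below background, a fold is given as a lower bound, with values of that group raised to the background threshold. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the 19 lists tested, out of 22 gene lists and 11 lists of cell type markers. camera with an estimated correlation and fry were run beside it. Totals, factors and controls were compared with exact two-sided permutation tests over 70 assignments of the samples, with Benjamini-Hochberg adjustment over the 6 measures compared.

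The text names genes by a rule: the 12 largest increases and 12 largest decreases among genes that passed the threshold with no overlap between the groups, a fixed set of T cell genes, up to 4 members of each gene list with the smallest p, and the 3 most abundant members of each marker list. The rule, the lists, the tests and the first set of alternatives were chosen before the data were examined. It selected 123 genes, of which 105 were tested. Some of these are not reported here. Of the fixed set, Cd8a, Cd8b1, Cd3e, Cd4, Gzmb, Prf1, Il2ra, Fasl, Tbx21 and Eomes were not analysed here, nor was Ssbp4, which was disrupted in the tumour cells and not in the cells measured.

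The samples carry numbers 1 to 4 in both groups. Deviations from the group means correlated between same-numbered samples at 0.454, 0.296, 0.465 and 0.197 across genes, which are not independent replicates, all above 0.1, so by the rule set for this check the numbers were taken to pair the samples. This pairing comes from the data and the numbering in the titles, since the labels do not say what the numbers mark. It was not told apart from a likeness of samples 1 and 2 and of samples 3 and 4, since sample 1 with sample 2 of the other medium correlated at 0.396 and 0.267, sample 3 with sample 4 at 0.424 and 0.255, and 5 of the 8 samples correlated best with their own number. The fit with the number as a block was an alternative. The labels also carry other numbers, 2, 3, 4 and 6 for wild-type medium and 8, 9, 10 and 12 for knockout medium. These may mark positions, which is not certain, and whatever they mark cannot be told apart from group. Counting noise was compared between samples by chi-square per degree of freedom. It was 2.05 to 4.53 between samples 1 and 2 or 3 and 4 of a group and 8.82 to 57.5 between the others of a group. No pair agreed within sampling noise, and all 8 samples were counted.

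Alternatives covered the pseudocount (0.5 and 10), the filter (none, or a mean of at least 50), scaling (median, quantile, reference genes, positive controls, T cell genes), limma without trend, robust or with array weights, thresholds of 1.5-fold or an adjusted p of 0.1, the block, each sample left out, samples 1 and 2 or 3 and 4 alone, those pairs averaged, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts. The steps were tested on simulated counts for this comparison, with 200 of 454 genes changed. limma recovered 46% of the 50 genes changed 1.5-fold, 82% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 7 calls among 239 unchanged genes. A planted list of 15 genes raised 2-fold had a camera adjusted p of 0.0193, and 0 of 18 other lists were called. Those other lists held only unchanged genes, the reference genes were unchanged, and genes and samples were simulated independently of one another. False calls of lists with correlated genes were therefore not tested. Nor were false calls of genes or lists with samples in close pairs or with changed reference genes.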

Results

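The comparison asked how medium conditioned by SSBP4-knockout melanoma cells, against medium from wild-type melanoma cells, changed the transcripts in cultures of activated CD8 T cells. Expression of 754 genes was measured in 4 samples per medium. Recovered counts summed to 346676, 310338, 309151 and 259954 in wild-type medium samples 1 to 4 and to 188174, 217944, 311980 and 320804 in knockout medium samples 1 to 4. The difference in these totals between the groups did not pass (exact permutation test, p = 0.3143, adjusted 0.4457 over 6 measures). All levels below are the authors' normalized values, given as mean ± SD with n = 4 per group.

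Most of the largest differences were in genes seen in 1 medium and at background in the other. Il1rl1, the receptor for IL-33, stood at 6367 ± 1555 in wild-type medium and 5.67 ± 1.44 in knockout medium, at least 269.7-fold lower (limma adjusted p = 1.77e-09). Cd34, a sialomucin of progenitor and vascular cells, fell from 4817 ± 251 to 4.45 ± 2.00, at least 209-fold. Kitl, the ligand of the receptor KIT, fell at least 59.5-fold, Ptgs2, the inducible cyclooxygenase, at least 66.3-fold, and the growth factor gene Fgf7 at least 37.1-fold. The growth factor receptors Pdgfra and Fgfr1 fell at least 18.2-fold and 10.97-fold, the mesenchymal transcription factor gene Prrx1 at least 22.7-fold, the collagen gene Col3a1 at least 17.5-fold, and Fscn1, an actin-bundling protein gene, at least 31.5-fold. The adhesion molecule gene Vcam1 fell at least 5.78-fold. Fosl1, a member of the AP-1 family, fell by 5.69 on the log2 scale (SE 0.20). Cd34, Pdgfra, Prrx1 and Col3a1 are not usual transcripts of CD8 T cells, and which cells this RNA came from was not determined.

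In the other direction, Apoe, which encodes apolipoprotein E, rose from 13.8 ± 2.40 to 1773 ± 133, at least 76.7-fold (limma adjusted p = 1.34e-09). Ptgds, a prostaglandin D synthase gene, rose from 21.0 ± 1.98 to 2284 ± 40.2, at least 97.6-fold. The metalloproteinase inhibitor gene Timp3 rose at least 31.7-fold, Rapgef4 at least 15.2-fold, the lysyl oxidase family gene Loxl2 at least 13.6-fold, the kinase gene Mapk13 at least 8.25-fold and the semaphorin gene Sema6d at least 3.18-fold. Fcgr4, an Fc receptor gene, and Irf8, a transcription factor gene, rose at least 7.31-fold and 6.21-fold. Cd74, the invariant chain of MHC class II, and the complement gene C4a rose by 4.89 and 4.05 on the log2 scale (SE 0.79 and 0.89), and H2-Aa, an MHC class II chain, at least 9.98-fold. These 3 genes and Irf8 and Fcgr4 varied widely in knockout medium. H2-Aa, for example, was 47.8, 44.0, 1364 and 1040 in samples 1 to 4. The 24 genes named so far had limma adjusted p of 0.00967 or less, but H2-Aa and C4a lost their calls with samples 1 and 2 averaged and samples 3 and 4 averaged (limma adjusted p = 0.0953 and 0.0521). Over the alternatives the fitted log2 change of H2-Aa ran from 2.18 to 6.34. Which cells the RNA of the genes higher in knockout medium came from was not determined either.

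**Figure D1:**
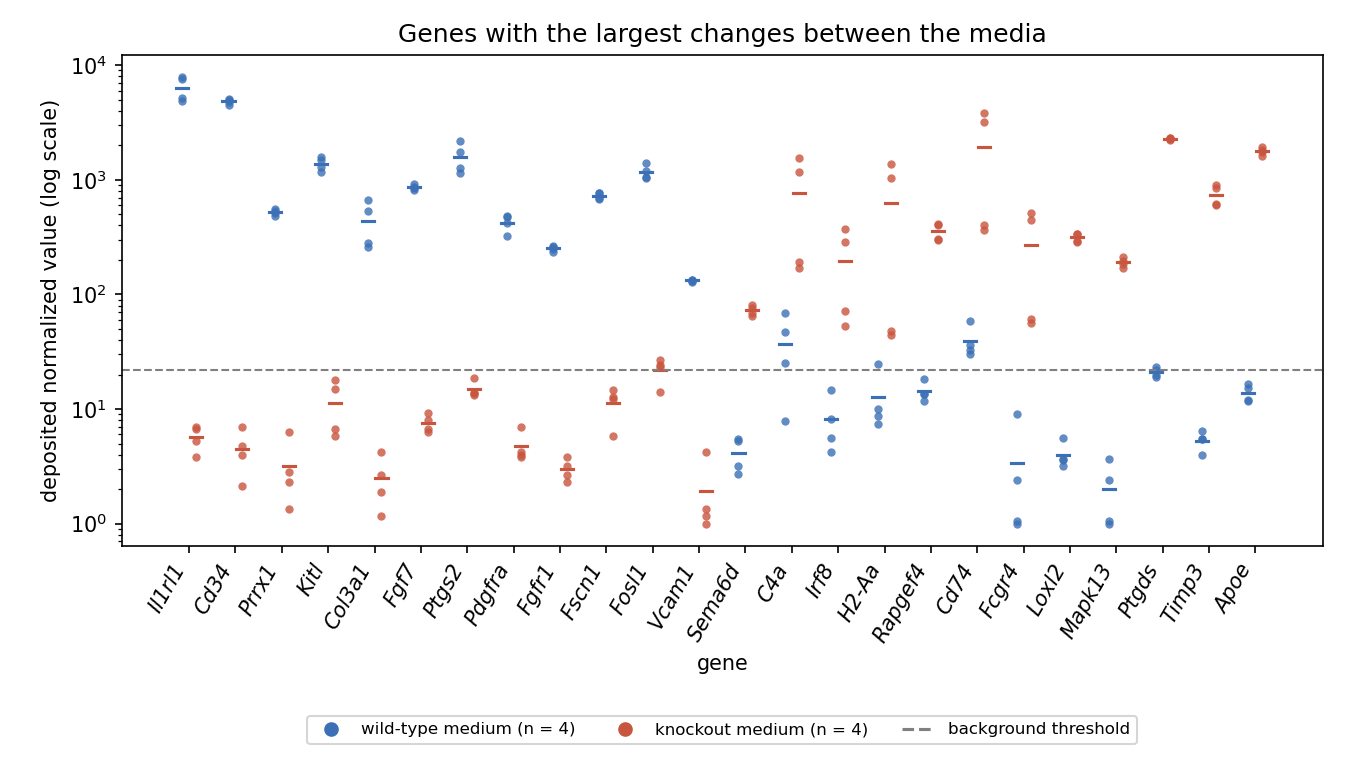
Deposited normalized values (log axis) of the 24 genes with the largest changes, 1 point per sample, with bars at the means of 4 samples per medium and a dashed line at the background threshold of 22.08. Il1rl1 and Cd34 lay between 4503 and 7888 in wild-type medium and below 7.0 in knockout medium, and Apoe and Ptgds lay at 1604 or above in knockout medium.

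In all, 325 of 454 tested genes changed, 213 higher and 112 lower in knockout medium (limma, adjusted p under 0.05), of which 139 and 70 changed by 2-fold or more. The 4 values of the groups did not overlap for 309 genes, where chance gives 2.86% if all 8 samples are separate. Samples 1 and 2, and samples 3 and 4, of a medium lay close together, so chance may give a larger share. Of the genes, 27 lay at background in all wild-type medium samples and above it in all knockout medium samples, and 23 the reverse. The median log2 change of all tested genes was 0.41, and the split into higher and lower depended on the scaling: it was 152 and 148 with median scaling, 166 and 136 with quantile normalization, 149 and 160 with edgeR and TMM, 156 and 152 with DESeq2, and 61 and 258 when samples were scaled to 6 T cell genes. Under that last scaling the signs of Cd44, Lag3, Fyn, Cd247, Tnfsf10, Ifngr1, Stat3, Stat6, Nfil3, Hif1a, Mif, Itgb1, Tnfrsf1a, Irf3, Tlr4 and Pdgfrb turned from higher to lower, and Nfil3 passed as lower. The calls of Batf, Ccr7, Cd27, Cd69, Ctla4, Cxcr4, Il18r1, Jak3, Ltb, Mx1, Nkg7, Ptprc, Stat4, Tlr1, Tnf and Vegfa were lost. Pdcd1, G6pdx, Fasn, C1qa and C3, which had no call in the main fit, passed as lower. Calls were also lost with median scaling, TMM or DESeq2 for Lag3, Mif, Nfil3, Pdgfrb and Tnfsf10, with quantile normalization for Lag3, Pdgfrb, Tnf and Tnfsf10, and with positive controls for Lag3, Tnf and Tnfsf10. With samples 1 and 2 averaged and samples 3 and 4 averaged, which leaves 2 values per medium, Batf, Ccl25, Cd274, Cd68, Cxcl10, H2-DMa, Ifngr1, Il18r1, Lag3, Mmp9, Mx1, Nkg7, Pdgfrb, Psmb8, Tnf and Tnfsf10 lost theirs.

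T cell genes, as named here, were higher in knockout medium. The name stands for the 6 tested members of the T cell receptor and co-receptor list. Whether other cells also held these transcripts was not tested. All 6 rose, with a median log2 change of 1.28, against 0.41 over all genes. Ptprc, the CD45 phosphatase, rose from 250 ± 60.7 to 660 ± 165, Cd247, the zeta chain of the receptor, from 79.6 ± 13.8 to 186 ± 32.1, and Cd27, a co-stimulatory receptor, from 53.5 ± 10.5 to 135 ± 34.5. The kinase Fyn rose by 0.88 on the log2 scale (SE 0.09). As a list they did not pass against other genes (camera adjusted p = 0.229, and 0.927 with an estimated correlation), and scaling to these same genes removed the difference by construction, with a median of 0.03. In the same samples Cd34, Prrx1, Col3a1 and Pdgfra fell at least 17.5-fold and Met rose by 2.69 on the log2 scale, so whether each T cell held more of these transcripts was not determined.

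Other lists of T cell function were mixed. Among 7 tested cytotoxic effector genes 4 rose and 3 did not pass. The granule protein gene Nkg7 rose by 1.60 on the log2 scale (SE 0.43) and the lymphotoxin gene Ltb by 1.66 (SE 0.15), while Gzma, a granzyme, was 86.1 ± 55.3 against 110 ± 29.2 (limma adjusted p = 0.314). Tnf rose from 17.1 ± 6.15 to 45.5 ± 25.0, a call lost without wild-type medium sample 1 or 2 or knockout medium sample 3 or 4 (limma adjusted p of 0.00728 to 0.0806 with each sample left out). The same 4 samples decided the call of Tnfsf10 (TRAIL), which rose (0.00995 to 0.0752). Ifng was 21.5 ± 21.8 against 15.03 ± 10.1 and Il2 2.68 ± 0.43 against 3.14 ± 2.62, both too low to be tested. Of 14 activation genes 7 rose and 3 fell: the early activation marker Cd69 rose by 1.61 on the log2 scale, the nuclear receptor Nr4a1 by 2.21 and the co-stimulatory receptor Tnfrsf9 (4-1BB) at least 4.84-fold, whereas Myc fell from 2725 ± 226 to 790 ± 43.9. Cd44 rose from 23.3 ± 5.41 to 48.7 ± 7.02.

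Among 7 tested genes of the inhibitory receptor and exhaustion list, which also holds ligands, 3 rose and 1, the ligand gene Cd274, fell. Adjusted over the list alone, 2 rose and 0 fell. Ctla4 rose from 66.2 ± 13.2 to 181 ± 25.8 and Vsir, the checkpoint receptor VISTA, from 57.1 ± 11.1 to 220 ± 57.3. Pdcd1 (PD-1) was 33.4 ± 29.6 against 26.5 ± 20.9 (limma adjusted p = 0.778), and lower by 1.48 on the log2 scale when scaled to T cell genes (limma adjusted p = 0.0325). Lag3 rose from 16.2 ± 9.66 to 32.6 ± 9.61, a call lost without wild-type medium sample 1, 2 or 4 or knockout medium sample 2, 3 or 4 (limma adjusted p of 0.0102 to 0.117 with each sample left out). Cd274 (PD-L1) fell from 2746 ± 811 to 1504 ± 645, a call lost without wild-type medium sample 2, 3 or 4 or knockout medium sample 1 or 2 (limma adjusted p of 0.0153 to 0.0961 with each sample left out). Havcr2 was 10.1 ± 8.15 against 24.4 ± 11.9 and Tigit 7.26 ± 4.29 against 8.66 ± 2.16, both untested. Of 8 naive and memory genes 6 rose and 1 fell, with Ccr7 up by 1.72 on the log2 scale and Bcl2 by 1.83, and Il6ra at least 1.59-fold lower. Of 8 type 1 genes 6 rose and 0 fell, among them Id2, up by 2.79, Stat4, up by 1.46, and Il18r1, up by 1.61. None of these 5 lists passed against other genes (camera adjusted p of 0.401 to 0.978). Scaled to T cell genes, the medians of the cytotoxic, activation and inhibitory lists turned negative, at -0.21, -0.38 and -0.63, and those of the naive and memory and type 1 lists shrank from 1.28 to 0.02 and from 1.36 to 0.12.

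Of 15 chemokine and homing receptor genes 11 rose and 0 fell, with Itga4, an integrin chain, at least 4.61-fold and Cxcr4 at least 2.63-fold higher. The list did not pass (camera adjusted p = 0.128, and 0.927 with an estimated correlation), although it did with the replicate number as a block (camera adjusted p = 0.0241, and 0.676 with an estimated correlation). Scaled to T cell genes, 1 of its genes was higher and 0 lower, and its median went from 1.36 to 0.10. Of 7 MHC class II genes 6 rose, with a median log2 change of 3.05, or 2.41 with genes at background in a medium set to their bound, but the list did not pass (camera adjusted p = 0.401, and 0.927 with an estimated correlation). The mean log2 value of its genes was 4.12, 4.43, 4.58 and 4.37 in wild-type medium samples 1 to 4 and 5.78, 5.85, 8.69 and 8.29 in knockout medium samples 1 to 4. H2-DMa rose from 40.6 ± 8.17 to 295 ± 216. Among 13 MHC class I genes 1 rose and 3 fell: H2-T23 rose by 3.19, and H2-M3, the immunoproteasome gene Psmb8 and the chaperone gene Calr fell by 1.97, 1.53 and 0.87 on the log2 scale. Of 11 interferon-stimulated genes 3 rose and 2 fell, or 2 and 2 adjusted over the list alone, with Mx1 up from 22.8 ± 4.89 to 130 ± 103, a call lost in samples 1 and 2 alone, and Cxcl10 down from 1433 ± 580 to 268 ± 191. The medians of the MHC class I and interferon lists, 0.17 and 0.18, changed sign under median, TMM, DESeq2 and T cell gene scaling, and camera, which sets a list against all other genes, put both on the lower side (adjusted p of 0.447 and 0.686). In samples 1 to 4 the mean log2 value of the interferon list was 7.90, 8.05, 8.43 and 8.42 in wild-type medium and 7.17, 7.43, 9.45 and 9.05 in knockout medium, and that of the MHC class I list 9.88, 10.06, 10.25 and 10.19 against 9.43, 9.59, 10.88 and 10.60. Both lists were thus lower in knockout medium in samples 1 and 2 and higher in samples 3 and 4, which a median over all samples hides.

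Cell cycle genes were lower in knockout medium: 5 of 6 fell and 1 rose, with a median log2 change of -2.02. Top2a, the topoisomerase of dividing cells, fell from 2989 ± 301 to 581 ± 66.6, Cdc20, a mitotic activator, from 356 ± 63.0 to 52.0 ± 7.56, and the replication helicase gene Mcm5 by 1.57 on the log2 scale (SE 0.09). The member that rose was Cdkn1a, the cell cycle inhibitor p21, from 121 ± 16.9 to 1560 ± 87.9. This was the only list to pass (camera adjusted p = 0.0468). The call was lost in 13 of 28 alternatives. Adjusted p ran from 0.0122 to 0.927 with camera and was 0.000127 with fry, which does not compare a list with other genes. Among those losing it were camera with an estimated correlation (adjusted p = 0.927) and scaling to the median, quantiles, positive controls or T cell genes. Under these scalings the median log2 change did not shrink, at -2.41, -2.31, -2.17 and -3.28. The fits without wild-type medium sample 2 or knockout medium sample 3 or 4 also lost it (camera adjusted p of 0.0554, 0.0795 and 0.0527). In the same samples Cd34, Prrx1, Col3a1 and Pdgfra, not usual in CD8 T cells, fell at least 17.5-fold, while T cell genes rose, so whether T cells or other cells held the lower cell cycle transcripts was not determined.

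Of 7 TGF-beta genes 5 fell and 1 rose, with the co-receptor gene Tgfbr3 down by 1.84 on the log2 scale, Skil by 0.82 and Smad2 by 0.75 (camera adjusted p = 0.0957). Of 7 chemokine genes 4 fell and 0 rose, including Cxcl1, from 154 ± 86.8 to 5.60 ± 1.39, at least 5.83-fold, Ccl2, from 84.4 ± 17.03 to 17.9 ± 7.28, at least 3.56-fold, and Ccl25, down by 0.71 (camera adjusted p = 0.128). Of 14 NF-kappaB and TNF genes 6 rose and 6 fell, with Traf2, Birc3 and Traf1 down by 1.77, 1.22 and 1.20 and Tnfrsf1a up by 0.94 (camera adjusted p = 0.401). Of 16 JAK-STAT and common gamma chain genes 10 rose and 3 fell, or 11 and 3 adjusted over the list alone, with Jak3 up by 1.73 and Il15ra and Il15 down by 2.05 and 1.78 (camera adjusted p = 0.585).

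Of 9 type 2 genes 3 rose and 2 fell, the latter being Il1rl1 and Areg, an EGF receptor ligand gene at least 3.11-fold lower (camera adjusted p = 0.705). The list's median of 0.10 and mean of -1.01 differ in sign, and the median was negative under every other scaling of the samples tried (median, quantile, positive controls, T cell genes, TMM and DESeq2). Both tested type 17 genes rose, Stat3 by 0.93 on the log2 scale and Batf from 11.3 ± 1.76 to 35.2 ± 17.4, at least 1.44-fold. Of 8 apoptosis genes 4 rose and 3 fell, with Bcl2 up and Bid down by 0.94, and the median of 0.67, or 0.41 with bounds, lay above 0 while camera put the list on the lower side (adjusted p = 0.838). Of 11 matrix and angiogenesis genes 3 rose and 6 fell, with Angpt2 up by 2.71 beside Timp3 and Vegfa (camera adjusted p = 0.401). All 3 tested hypoxia genes rose, namely Vegfa by 1.70, Hif1a by 1.05 and Mif by 0.78. Of 4 metabolic genes Apoe alone changed, although Fasn passed as lower with TMM and DESeq2, and Fasn and G6pdx did when scaled to T cell genes. G6pdx, an enzyme gene of the pentose phosphate pathway, was 485 ± 59.1 against 598 ± 151 (limma adjusted p = 0.2, and 0.0470 with the replicate number as a block). Of 3 complement genes C4a alone changed, although C3 and C1qa passed as lower when scaled to T cell genes. Of 11 Toll-like receptor and inflammasome genes 6 rose and 2 fell, with Irf3 up by 1.21 and Tlr4 by 0.86 on the log2 scale, Tlr1 at least 2.28-fold higher and Irf5 at least 2.57-fold lower (camera adjusted p = 0.686). Scaled to T cell genes, the medians of the apoptosis, JAK-STAT and Toll-like receptor lists turned negative, at -0.59, -0.61 and -0.40. For lists with no second count given, the counts adjusted over the list alone were the same.

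**Figure D2:**
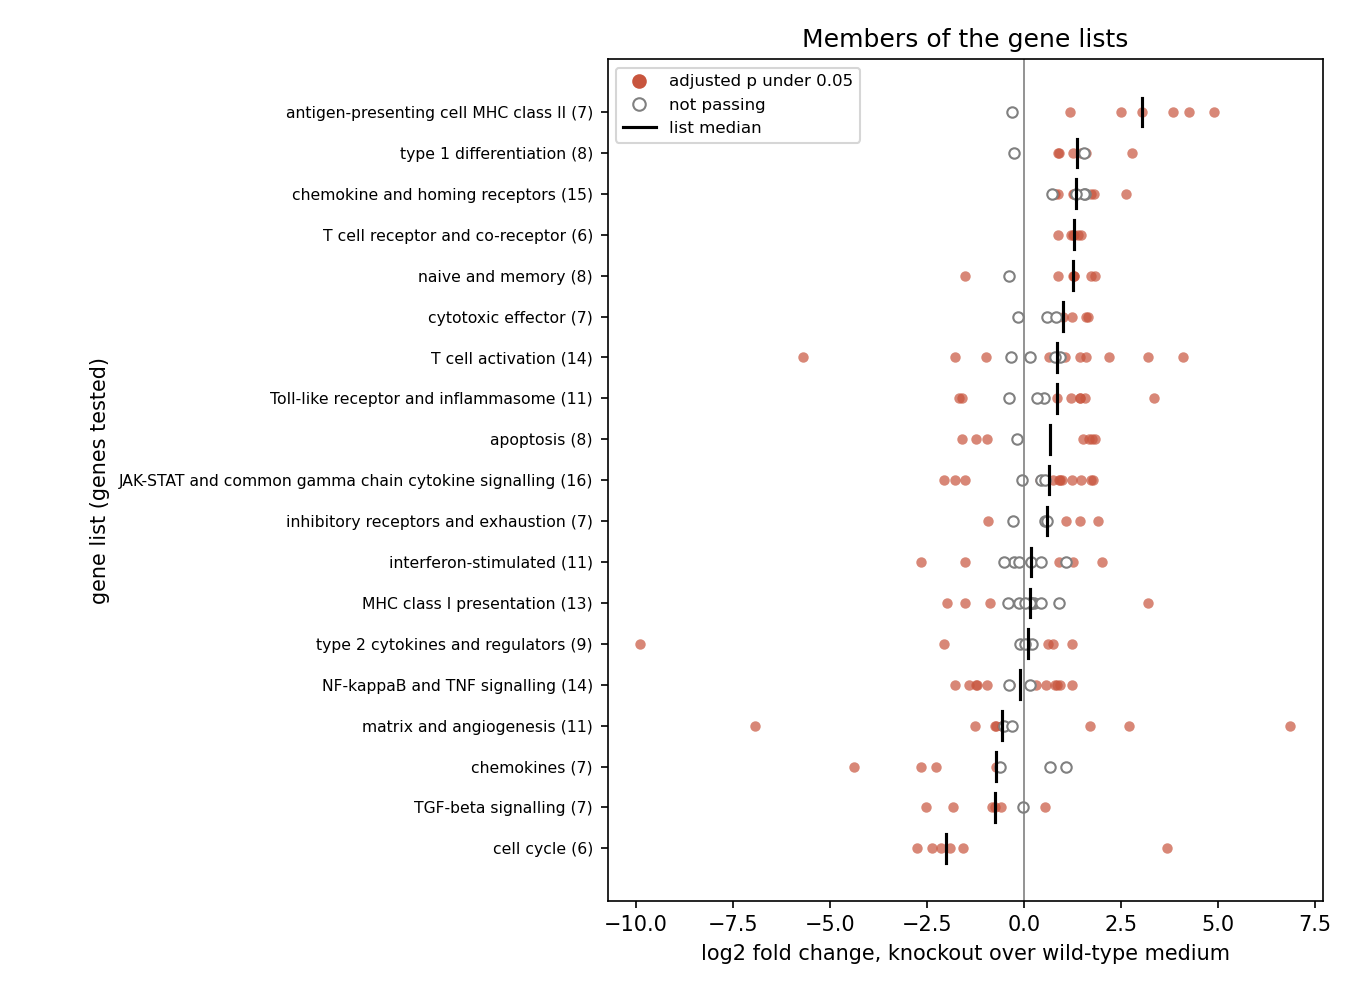
Log2 fold changes (knockout over wild-type medium, 4 samples each) of the tested members of 19 lists, with filled points for adjusted p under 0.05, open points for the rest and a bar at each list's median. Medians ran from -2.02 for cell cycle genes to 3.05 for MHC class II genes.

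Most markers of other cell types had too low a mean to be tested. Of 19 measured macrophage and monocyte markers 4 were tested, of which Fcgr4 rose, Cd68 fell by 0.47 on the log2 scale and C1qa did not change past the threshold (limma adjusted p = 0.926), with 1 higher and 0 lower adjusted over the list alone. The Cd68 call was lost without wild-type medium sample 2, 3 or 4 or knockout medium sample 1 or 3 (limma adjusted p of 0.0135 to 0.103 with each sample left out). Of 12 neutrophil markers only Mmp9 was tested. It fell by 0.73, a call lost without wild-type medium sample 1 or 2 or knockout medium sample 4 (limma adjusted p of 0.0145 to 0.0823 with each sample left out). Neither the 3 B cell, the 14 mast cell, basophil and eosinophil nor the 1 erythroid and platelet marker measured reached the mean needed for testing, with Ms4a1 at 19.9 ± 3.48 in wild-type and 22.3 ± 7.86 in knockout medium. Among the mast cell, basophil and eosinophil markers Gata2 was 30.3 ± 5.54, above background in all 4 wild-type medium samples, against 10.1 ± 4.36, below it in all 4 knockout medium samples. Of 11 dendritic cell markers only Ccr7, which T cells also express, was tested. Of 3 NK cell markers the 2 tested, Klrk1 and Gzma, did not pass, although Klrk1 did with the replicate number as a block (limma adjusted p = 0.00535). Of 3 CD4 and regulatory T cell markers Ctla4 rose. Of 6 endothelial and fibroblast markers Col3a1 and Pdgfra fell and Pdgfrb rose, from 22.3 ± 1.34 to 36.8 ± 8.15, a call lost in 6 of 26 alternatives and reversed in sign in 1 (limma adjusted p of 0.00245 to 0.394). Met, the 1 gene of the melanoma marker list that was measured, rose from 409 ± 37.5 to 2679 ± 546. Which cells held it was not determined.

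The 20 reference genes used for scaling also differed between the media. Of these, 6 were higher and 5 lower. Scaling to their geometric mean balances rises with falls by construction, so these counts depend on it. The log2 changes ran from -1.89 for Eef1g, a translation elongation factor gene, to 0.81 for Eif2b4, both chosen after their values were seen. Eef1g was lower under every scaling tried, and Eif2b4 was lower, by 0.44, when scaled to T cell genes. The geometric mean of the positive controls was 522 ± 29.1 in wild-type medium and 474 ± 36.5 in knockout medium (exact permutation test, p = 0.1143, adjusted 0.2286), and the mean of the negative controls was 9.53 ± 0.92 and 8.22 ± 2.50 (exact permutation test, p = 0.3714, adjusted 0.4457). Samples of 1 medium correlated at 0.936 to 0.990 across genes, which are not independent replicates, and samples of different media at 0.525 to 0.634.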

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

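The test for a sample lying apart from the other 3 of its group was run on 218 groups, of named genes and 4 sample measures, and 6 groups passed, where chance gives about 1 in 20 groups, or 10.9 here. The statistic is the gap to the nearest sample divided by the range, on log2(value + 1) for genes and log2 for the sample measures, set against Dixon's 95% critical value. In knockout medium, Ptgs2 was 18.6 in sample 1 against 13.3 to 13.9 in the others (0.866), and Vcam1 was 4.24 in sample 3 against 1.00 to 1.33 (0.841), all below background. In wild-type medium, Ifngr1 was 595 in sample 3 against 413 to 439 (0.831), Nfil3 was 681 in sample 1 against 610 to 619.6 (0.858), and Mx1 was 30.1 in sample 1 against 19.9 to 20.9 (0.88). The geometric mean of the positive controls was 565 in wild-type medium sample 1 against 505 to 509.98 in the others (0.909).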

How the results depend on the processing

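The T cell gene and positive-control scalings, the fits on pairs of samples, the edgeR and DESeq2 fits and the estimated correlation joined to other alternatives were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of 325, 213 higher and 112 lower, under all alternatives but scaling to T cell genes. In total the fewest were 144 higher and 80 lower with the pairs averaged, and the most 246 and 118 without a filter. The most lower genes among these alternatives were 160, beside 149 higher, with TMM. When each sample was left out, 306 to 334 genes changed. Scaling to 6 T cell genes gave 61 higher and 258 lower and called 34 of the 325 genes in the opposite direction. None of the 325 was called in the opposite direction under any other alternative. Relative to a median log2 change of 0.41, that median was 0.02 with median scaling, 0.11 with quantile normalization, 0.26 with positive controls, -0.07 with TMM, 0.00 with DESeq2 and -0.85 with T cell genes. Rescaling to the reference genes moved nothing, since the deposited values are already scaled to them. The edgeR fit with the authors' factors called 217 higher and 112 lower.

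Of 2684 values of the named genes kept for reporting, under the alternatives, 2563 kept their direction and side of the threshold, 92 lost the threshold, 7 gained it and 22 reversed. Those that gained it with no change of sign were Pdcd1, lower with T cell genes, Klrk1 with the replicate block and in samples 1 and 2 or 3 and 4 alone, G6pdx with the block and in samples 3 and 4 alone, and Gzma in samples 1 and 2 alone. Among the reversed values, G6pdx, Fasn, C3, C1qa and Nfil3 passed as lower with T cell genes (limma adjusted p = 0.000672, 8e-04, 0.0219, 0.00606 and 0.0353). Scaling to T cell genes turned Lag3 to -0.13, Cd44 to -0.18, Fyn to -0.39, Cd247 to -0.048, Tnfsf10 to -0.21, Ifngr1 to -0.40, Stat6 to -0.028, Nfil3 to -0.64, Stat3 to -0.34, Hif1a to -0.22, Mif to -0.49, G6pdx to -0.99, Fasn to -1.19, Itgb1 to -0.50, Tnfrsf1a to -0.33, C3 to -1.09, C1qa to -1.20, Irf3 to -0.052, Tlr4 to -0.40 and Pdgfrb to -0.55. This scaling sets the mean of 6 genes that rose to no change, so it lowers all others by its own construction. Fasn became -0.40 with TMM (edgeR adjusted p = 0.00813) and -0.33 with DESeq2 (DESeq2 adjusted p = 0.0162), so it passed as lower in both. Both fits lower the median of all genes.

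The 1 lower and 0 higher gene lists were less stable. The number of lower lists was 0 with a pseudocount of 10, a mean of at least 50, median scaling, quantile normalization, positive controls, T cell genes, samples 1 and 2 alone or an estimated correlation (alone, with T cell genes or with the replicate block), 2 without a filter and 2 with samples 3 and 4 alone, and 0 to 1 when each sample was left out. The number of higher lists was 1 with T cell genes (MHC class II, adjusted p = 0.0204, and 0.885 with an estimated correlation), 2 with samples 3 and 4 alone and 1 with the replicate block (chemokine and homing receptors). fry, which does not compare a list with other genes, gave 10 higher and 4 lower and turned the matrix and angiogenesis list to higher (adjusted p = 0.00522). The cell cycle list lost its call in 13 of 28 alternatives, with adjusted p from 0.0122 to 0.927 with camera and 0.000127 with fry. Beyond the causes named, the cause was not tested. The replicate block gave 227 genes higher and 115 lower, made G6pdx pass (adjusted p = 0.0470) as well as Klrk1, and changed no call of a named gene or list beyond these and the chemokine and homing receptor list. For genes with a group mean below the background threshold of 22.08, such as Lag3, the log2 changes here are fitted, and the change itself has only a bound.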

Other observations

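The test of the splits of the samples was set before its result was seen. The other tests of explanations here, and the genes named in the next 2 paragraphs, were chosen after the values were seen.

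Among genes outside the naming rule, Ttk, a spindle checkpoint kinase gene, fell from 174 ± 5.56 to 23.4 ± 3.59 (SD, n = 4), and Kif20a, a kinesin gene of cytokinesis, from 302 ± 53.5 to 52.3 ± 11.5. Cav1, the main protein of caveolae, fell from 2308 ± 384 to 137 ± 17.6, Emp1 from 871 ± 165 to 39.6 ± 3.94, and the transcription factor gene Klf4 from 624 ± 44.4 to 23.1 ± 6.59. In the other direction, Ctnnb1 (beta-catenin) rose from 826 ± 45.2 to 4929 ± 337, Cdh2 (N-cadherin) from 82.4 ± 2.31 to 647 ± 40.9, Sirpa, a receptor for CD47, from 61.7 ± 6.71 to 821 ± 57.9, and the transcription factor gene Ets1 from 425 ± 33.7 to 2317 ± 401. The SE of these log2 changes was 0.079 to 0.205, and all had limma adjusted p of 4.39e-06 or less.

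Samples with numbers 1 and 2 lay close together in both media, as did those with numbers 3 and 4, and the labels do not say what the numbers mark. Ccl5, a chemokine gene, was 310, 454, 1206 and 878 in wild-type medium samples 1 to 4 and 335, 388, 2928 and 2516 in knockout medium samples 1 to 4. Isg15, an interferon-stimulated gene, was 593, 601, 949.8 and 896 and then 271, 315, 1533 and 1177. Cd74 was 30.1, 36.2, 58.2 and 32.9 and then 364, 401, 3815 and 3208. Ptprc was 198, 222, 337 and 243 and then 480, 622, 879 and 659. What sets these samples apart was not tested.

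The 8 samples can be split into 4 and 4 in 35 ways. The real split gave 325 changed genes, against at most 0 in the others. Chance assignment can be excluded only if all 35 splits count alike. Every other split mixes the media, which puts their difference into the spread within groups, so low counts there were likely. The splits do not count alike where the numbers pair the samples. Of the 8 splits that part all 4 pairs of same-numbered samples, the highest other than the real one also gave 0. But 8 splits are too few for a share under 0.05. Nor do the splits count alike if samples 1 and 2, or 3 and 4, of a medium are not separate, which was not settled. Chance assignment then cannot be excluded for the count of genes. For the count of gene lists, 23 of 35 splits gave at least the 1 list of the real split, and the highest of the others gave 7, several times the real count, which points to a structure of the samples. Setting samples 1 and 2 of both media against samples 3 and 4 gave 5 lists and 0 genes, and the splits that part all 4 pairs gave at most 3 lists. So chance assignment cannot be excluded for that count.

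The pattern that most calls for a closer look is the set of 15 genes at background in 1 medium and at least 8-fold above it in the other, 10 of them high in wild-type medium and 5 in knockout medium. The authors' scaling is argued against as its whole cause, since a factor per sample moves every gene the same way and 5 of the 15 genes moved against the other 10. If T cells were the only source of these genes, in fixed proportion to their T cell genes, each gene should follow the T cell list within its medium with a slope of 1. The slope's 95% interval lay below 1 for 10 of the 15 genes, such as Col3a1 (-1.63, SE 0.48), which goes against this for those 10. It held 1 for the others, such as Il1rl1 (0.85, SE 0.27) and Ptgs2 (1.01, SE 0.34). Each slope rests on 4 samples that lie in close pairs, which the intervals ignore, so for the whole set this stays open. RNA of other cells also stays open. Negative selection came before the culture and should reduce other spleen cells, but not anything carried in with the medium. T cell receptor genes that vary on their own within T cells stay open too. So do an effect of the medium, anything that went with position or culture, and a full exchange of the group labels. These values would not show such an exchange, and none of these was tested.

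The reference genes differed between the media by a span of 2.701 in log2 change (SE 0.176 for the difference of the outer 2), from Eef1g to Eif2b4. No factor per sample can alter this span, so an unsuitable scaling factor alone cannot account for it. What lies behind it was not tested.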
